A study of Homo sapiens with 3 samples.

How the data were processed

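AB12 is a mouse malignant mesothelioma cell line. The series holds 3 RNA libraries of it: 1 labelled shSC, taken as the control hairpin, and 2 labelled shNF2, which carry the numbers 20 and 21 and are called library 20 and library 21 here. The column names of the deposited values also mark shSC as WT and both shNF2 libraries as KD. The labels do not say what 20 and 21 stand for, nor that the libraries came from separate cultures. The p-values of single genes therefore measure only the spread between these libraries, which may be technical. The organism label reads human, whereas the gene identifiers in the table are mouse Ensembl identifiers and the submitters' processing notes name the mouse build mm10; the values were treated as mouse. Per the labels' protocols, cells were grown in RPMI with 10% serum, polyA RNA was selected, and stranded TruSeq mRNA libraries were read as pairs on a HiSeq 2500.

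The authors deposited 1 table of gene signal, which its name describes as scaled counts. The submitters' processing notes name cutadapt 1.6, STAR 2.5.0a, HTSeq 0.5.3 and DESeq 1.22.1, with no role or order. Per the values in the deposited table, each column is a whole number of reads divided by 1 factor per library: with a tolerance of 0.001 reads, 100% of the values in every library came out whole, with factors of 1.03 for shSC, 0.956 for library 20 and 1.03 for library 21. The table holds 13936 genes. The smallest total over the 3 libraries was 15 reads, so low genes had been removed before deposit by a filter that is not given in the sources used here. A further 4 rows name no gene (not uniquely aligned, ambiguous, no feature, not aligned); they held 48.6%, 48.7% and 47.7% of the reads summed over all rows in shSC, library 20 and library 21 and were left out. Reads assigned to genes numbered 29532600, 25837151 and 26829163. The labels name a stranded kit, but the strand setting of the counting is not given in the sources used here.

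Groups came from the labels. The tests, alternatives and 37 gene lists were fixed before the data were examined. For shNF2 against shSC, limma 3.58.1 in R 4.3.3 was run with a variance trend on log2(scaled count + 1) for the 12813 genes with a mean of at least 10, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on that scale, which understates the change of low genes. The spread came from 1 residual degree of freedom between the shNF2 libraries, moderated over genes (11.9 prior degrees of freedom), and the lone shSC library was assumed to vary alike. An exact test of 2 libraries against 1 cannot go below 1/3. The median standard error of a log2 fold change was 0.26. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered reads as alternatives.

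Lists were tested with camera at its preset correlation of 0.01 and again with an estimated correlation, with adjustment over lists. At the preset correlation camera compares the statistics of genes in a list with those of other genes. Its spread is that across genes, so genes act as the replicates and a small p-value does not show that a shift would recur in other libraries. The median of each list was also placed among 10000 random lists of the same size matched on mean expression in 20 bins. Lists with under 3 tested members had no camera test. Genes named in the text were Nf2, 7 Hippo pathway genes or targets, the 10 largest rises and 10 largest falls by the smaller of both libraries' fold changes among genes passing the test with a mean of at least 100 (unnamed gene models skipped), and up to 4 members with the smallest p in each list. The largest rises and falls also had to move the same way in both libraries. Genes outside the rule for named genes are said to have been chosen after their values were seen. A fold change shared by both shNF2 libraries includes the chance value of the shSC library. For this reason 100 sets of unchanged libraries were simulated with negative binomial counts at the real means. Dispersions came from edgeR's trend over mean level, which rests on the spread between the shNF2 libraries. Genes noisier than that trend, and any extra spread of shSC, are therefore not in the simulations.

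Alternatives were other pseudocounts, filters and scalings (TMM, quantile), limma without a trend or with robust moderation, edgeR, DESeq2, other fold limits, each shNF2 library left out, and an estimated correlation for lists. After the data had been seen, a correction for transcript length and GC was added. No mouse annotation was used here, so length and GC were the medians of human GENCODE v29 protein-coding transcripts of the same symbol, or of another symbol of the same gene, as stand-ins. These covered 10337 tested genes (80.7%) and 89 of the 108 genes that passed. Each library's trend was fitted with mgcv 1.9.3 and subtracted. Matching by symbol alone had been run first and covered 9978 genes (77.9%). No gene coordinates are given.

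The scripts were tested on simulated data for this comparison, with 200 of the genes changed in each of 5 simulations and 12661 genes tested on average. limma recovered 41.7% of the genes changed 2-fold and 91.4% of those changed 4-fold, with 5.80% of its calls false. For edgeR these were 42.7%, 92.2% and 5.45%, and for DESeq2 30.7%, 80.9% and 1.62%. A planted shift of a list of 30 genes was found in 5 of 5 simulations at the preset correlation and a random list in 0. Counts were drawn for each gene independently, at the same dispersion trend as above. These shares therefore do not cover noisier genes, and the list results do not cover lists whose members move together. With an estimated correlation the planted list was found in 0 of 5 (smallest unadjusted p 0.0715). A planted GC trend with a mean Spearman's rho of -0.548 was reduced to -0.0045 by the correction. Genes of families with near-identical copies (Speer3, Oas1a, Mcpt1, Mcpt2, Lilr4b, ribosomal proteins, Tmsb4x) are uncertain. Reads that match more than 1 copy may have gone to the row of reads not uniquely aligned, which was left out.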

Results

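The transcriptome of AB12 mouse mesothelioma cells labelled shNF2 was compared with that of cells labelled shSC, as the series' design states. NF2 encodes merlin, a membrane-linked tumour suppressor that acts upstream of the Hippo pathway. There was 1 shSC library and there were 2 shNF2 libraries, with 29532600, 25837151 and 26829163 reads in genes for shSC, library 20 and library 21. Values are scaled counts as deposited; shSC has no replicate.

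Nf2 was lower in both shNF2 libraries. It had 1539 scaled counts in shSC, 486 in library 20 and 458 in library 21, a log2 fold change of -1.70 ± 0.24 (SE; limma adjusted p = 0.00555). Yap1 and Wwtr1, the transcriptional coactivators that the Hippo pathway restrains, did not pass the test, with log2 fold changes of 0.16 and -0.18. The kinases Lats1 and Lats2 had log2 fold changes of 0.17 and 0.54 and did not pass either. The limma call on Nf2 was lost under quantile normalization (log2 fold change -1.72, adjusted p = 0.496) and without a variance trend (adjusted p = 0.187).

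In shNF2, 53 genes rose and 55 fell among 12813 tested, and all 108 moved the same way in both libraries. The shared direction follows largely from the test, whose spread is the difference between the shNF2 libraries, and from their shared shSC library. It is not a replication. Cyr61 and Ctgf, well-known targets of YAP and TAZ, were among the genes that rose. The matrix metalloproteinase gene Mmp13, the NADPH oxidase gene Nox1 and the EGF receptor ligand gene Btc were among those that fell. At an unadjusted p under 0.05 there were 1188 genes. edgeR called 29 higher and 52 lower, DESeq2 41 and 57, and 67 genes were called by limma, edgeR and DESeq2. limma called 0 genes under quantile normalization (882 at an unadjusted p under 0.05) and 0 without a variance trend (1036), and without the filter on low values it called 110 higher and 122 lower.

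The largest rises included chemokines, an aldehyde dehydrogenase and adhesion or guidance genes. Ccl9 rose from 1441 scaled counts in shSC to 6061 and 6170 in libraries 20 and 21 (log2 fold change 2.08 ± 0.21, SE, adjusted p = 0.000993). Ccl17 rose from 36.0 to 249 and 176 (2.51). Aldh1a1, which makes retinoic acid from retinal, rose from 834 to 3188 and 8594 (log2 fold changes of 1.93 and 3.36), a call lost with DESeq2 (adjusted p = 0.529) and robust moderation (0.485). Sema3a, an axon guidance cue, rose by a log2 fold change of 2.47, the receptor phosphatase gene Ptprf by 2.22 and the keratin gene Krt7 by 2.19. Tigit, Stxbp6 and Speer3 had log2 fold changes of 1.90, 2.04 and 2.19. Fam198b had 1.80 in library 20 and 3.47 in library 21, and its call was lost with TMM (adjusted p = 0.0642), edgeR (0.0651), robust moderation (0.558) and DESeq2 (0.723). Speer3 belongs to a family of near-identical copies.

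The largest falls included Mmp13, a collagenase, from 57023 scaled counts in shSC to 6389 and 10898 in libraries 20 and 21 (log2 fold change -2.77 ± 0.28, SE, adjusted p = 0.000993). Nox1 fell from 16461 to 3071 and 2921 (-2.46), and Btc, which encodes betacellulin, from 4250 to 948 and 1058 (-2.08). Aldh1a3, another retinaldehyde dehydrogenase gene, fell from 460 to 48.1 and 59.3 (-3.08). The adhesion gene Ceacam1 had a log2 fold change of -2.73 and the tetraspanin gene Cd53 -2.33. The annexin gene Anxa10 had -4.14 in library 20 and -2.83 in library 21, and its call was lost with robust moderation (adjusted p = 0.133) and DESeq2 (0.137). The chemokine receptor gene Ccr1 had -3.36 and -1.92 in these libraries, and its call was lost with robust moderation (0.183). The interferon-inducible gene Ifi27l2a had -1.94 and -3.46, with a call lost under TMM (0.0727) and robust moderation (0.131). Lilr4b had -4.33 and -2.12, with a call lost under TMM (0.0727), robust moderation (0.586) and DESeq2 (1).

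**Figure D1:**
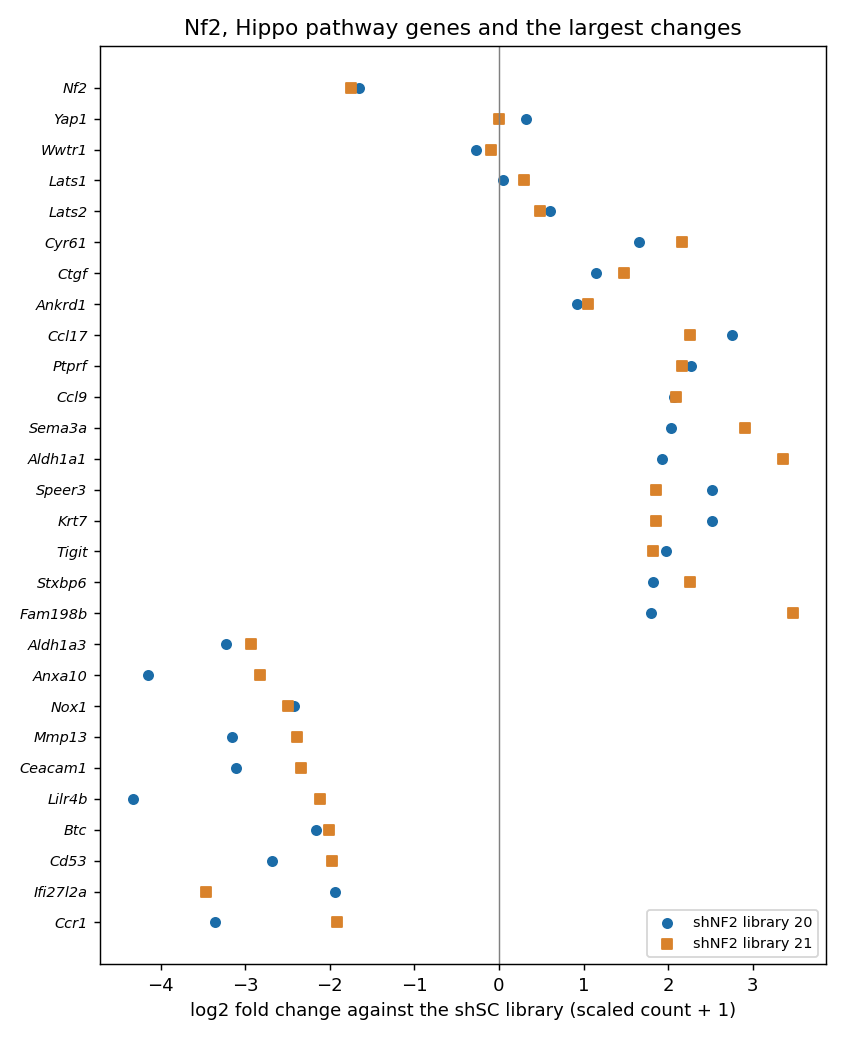
Log2 fold change against shSC on the log2(scaled count + 1) scale for Nf2, 7 Hippo pathway genes or targets, and the 10 largest rises and 10 largest falls; circles are library 20 and squares library 21. Nf2 lies at -1.66 and -1.75. The 20 largest changes lie on the same side of 0 in both libraries because the choice of genes required it.

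YAP/TAZ-TEAD targets rose as a list at the preset correlation (camera adjusted p = 2.11e-07, and adjusted p = 0.852 with an estimated correlation). The latter test has 1 residual degree of freedom and passed a planted list in 0 of 5 simulations, so missing the threshold there, for this list and those that follow, does not show that a list did not move. Of 24 tested members 5 rose and 1 fell over all genes tested, and 9 were higher and 1 lower adjusted over the list alone. Cyr61 rose from 445 to 1404 and 1993 scaled counts (log2 fold change 1.91), Ctgf by 1.31, Crim1 by 1.47, Amotl2, which binds and restrains YAP, by 1.27 and Ankrd1 by 0.99. The call on Ankrd1 was lost with robust moderation (adjusted p = 0.0538), TMM (0.0731) and edgeR (0.0952), and that on Ctgf with edgeR (0.0516). F3, which encodes tissue factor, fell from 1696 to 672 and 676 (-1.33). The list's median log2 fold change was 0.51, at percentile 100 of random lists. G2/M genes, p53 targets and SRF and actin genes also lay at percentile 100. Chemokines and cytokines, ERK feedback genes and mitochondrially encoded genes lay at 0. Random lists and the simulated lists drew genes independently, so neither covers members that move together. Among the 13 lists passing at the preset correlation, the estimated correlation ran from -0.0267 (ERK feedback) to 1 (mitochondrially encoded genes). With 1 residual degree of freedom, this value reflects only whether members differ in the same direction between the shNF2 libraries. It therefore cannot measure how strongly members move together.

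G2/M genes were higher as a list at the preset correlation, with no member passing alone (camera adjusted p = 8.49e-09, and adjusted p = 0.852 with an estimated correlation). All 32 members were tested, 26 were above shSC in both libraries, and 0 passed over all genes tested or adjusted over the list alone. Kif11, a spindle motor, had a log2 fold change of 0.82, Anln 0.82, Top2a 0.72 and Tpx2 0.68. The list's median was 0.43 (0.40 in library 20, 0.48 in library 21). The 33 S-phase genes had a median of 0.09 and did not pass (adjusted p = 0.404), and Lig1 and Pola1 had log2 fold changes of 0.56 and 0.60.

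Further lists were higher in shNF2 at the preset correlation, each with adjusted p = 0.852 with an estimated correlation. Of 28 p53 targets 0 passed over all genes tested or adjusted over the list alone (camera adjusted p = 0.00555, median 0.33 in library 20 and 0.16 in library 21), and Fas, Plk2 and Mdm2 had log2 fold changes of 0.88, 0.70 and 0.50. Of 28 SRF and actin cytoskeleton genes 0 passed over all genes tested and 1 adjusted over the list alone, the calponin gene Cnn2 at 1.17 (camera adjusted p = 0.0198, median 0.11 in library 20 and 0.35 in library 21). Cnn2 passed with DESeq2 (adjusted p = 0.0332) and without the filter on low values (0.00739). Of 34 cholesterol synthesis genes 0 passed either way (camera adjusted p = 0.0259), and Fads2 and Hmgcs1 had log2 fold changes of 0.66 and 0.47. The list's median was 0.31 in library 20 and 0.06 in library 21, and this call was lost under quantile normalization (adjusted p = 0.055). Of 14 collagen and matrix genes, 2 rose and 1 fell, and 4 were higher and 1 lower adjusted over the list alone (0.0464). Col8a1 rose by 1.06, a call lost with TMM (0.0622) and edgeR (0.0776). Has2, which makes hyaluronan, had -4.21 in library 20 and -2.27 in library 21, and its call was lost with TMM (0.0727) and robust moderation (0.21). Sparc had 1 read in shSC and 20 and 22 reads in shNF2, a ratio of 21.7 with an exact 95% counting interval of 3.69 to 879. Its call was lost with TMM (0.0523), length and GC correction (0.059), edgeR (0.0851), pseudocount 10 (0.111) and DESeq2 (0.663). The matrix call was lost with pseudocount 10 (0.0759), a mean of at least 50 (0.316) and quantile normalization (0.157).

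Interferon-stimulated genes fell as a list at the preset correlation (camera adjusted p = 0.00456, and adjusted p = 0.852 with an estimated correlation). The list's median was -0.36 in library 20 and -0.08 in library 21. Of 42 tested members 2 fell, and adjusted over the list alone 6 were lower and 1 higher. Oas2 fell from 507 to 123 and 170 scaled counts (log2 fold change -1.80) and Irf7 from 1146 to 506 and 355 (-1.43); Oas1a and Isg15 had values of -1.06 and -0.91, and Oas1a passed with DESeq2 (0.0317) and without the filter (0.0125). Chemokines and cytokines were lower as a list (0.0163, and adjusted p = 0.852 with an estimated correlation), although members went both ways. Of 29 tested, 2 rose and 2 fell, and 4 were higher and 8 lower adjusted over the list alone. Ccl9 and Csf1 (1.19) rose and Clcf1 (-1.17) and Vegfc (-1.93) fell. The call on Clcf1 was lost with TMM (0.0542) and that on Vegfc with DESeq2 (0.0503) and TMM (0.0643). The list's median was -0.11 in library 20 and -0.66 in library 21, and this call was lost under quantile normalization (adjusted p = 0.0775).

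ERK feedback and immediate early genes were lower as a list (camera adjusted p = 0.002, and adjusted p = 0.852 with an estimated correlation), with a median of -0.18 in library 20 and -0.34 in library 21. Of 34 tested, Spry4, a feedback inhibitor of receptor kinase signalling, fell from 701 to 210 and 236 scaled counts (-1.65), and 1 was lower adjusted over the list alone. Egr3, Spred3 and Klf4 had log2 fold changes of -1.74, -0.99 and -0.71. Hypoxia response genes were lower as a list (0.00151, and adjusted p = 0.852 with an estimated correlation). Of 19 tested 0 passed over all genes tested and 1 was lower adjusted over the list alone, Ankrd37 at -1.25, which passed without the filter (0.0327); Ndrg1, Hilpda and Bnip3 had values of -0.75, -0.70 and -0.62.

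Mitochondrially encoded genes were lower as a list (camera adjusted p = 0.000292, and adjusted p = 0.852 with an estimated correlation). Of 9 tested, 8 were below shSC in both libraries, 0 passed over all genes tested and 5 were lower adjusted over the list alone. mt-Co1 had 253920 scaled counts in shSC, and mt-Nd4, mt-Nd1, mt-Cytb and mt-Co1 had log2 fold changes of -0.74, -0.70, -0.73 and -0.79. This call was lost under quantile normalization (adjusted p = 0.101). Of 55 ribosomal protein genes 0 passed either way, and the list was lower (adjusted p = 0.00011, and adjusted p = 0.852 with an estimated correlation) with a median of -0.05 in library 20 and -0.52 in library 21; it was lost under quantile normalization (adjusted p = 0.609). Rpl19, Rpl34, Rpl13a and Rps27a had log2 fold changes of -0.55, -0.60, -0.60 and -0.52. Of 40 oxidative phosphorylation genes 0 passed either way (0.0259, and adjusted p = 0.852 with an estimated correlation), with medians of -0.09 in library 20 and -0.21 in library 21, Uqcrq at -0.68 and Cox7b at -0.47, and this call too was lost under quantile normalization (adjusted p = 0.477).

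Library 21 differed from shSC in relation to the GC content and length of the transcripts. Across genes, which are not independent replicates, Spearman's rho between GC and the log2 fold change was -0.373 in library 21 and -0.037 in library 20. The median log2 fold change of library 21 ran from 0.19 in the eighth of genes with the lowest GC to -0.31 in that with the highest. With length, rho was 0.208 in library 21 and 0.036 in library 20, and the median of library 21 was -0.07 in the eighth of genes with the shortest transcripts and 0.18 in that with the longest. Stand-in transcripts of the G2/M list had a median GC of 43.4%. Those of the ribosomal protein list had 51.1%, near the group at 51.7% whose median in library 21 was 0.02, and a median length of 705 bases.

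**Figure D2:**
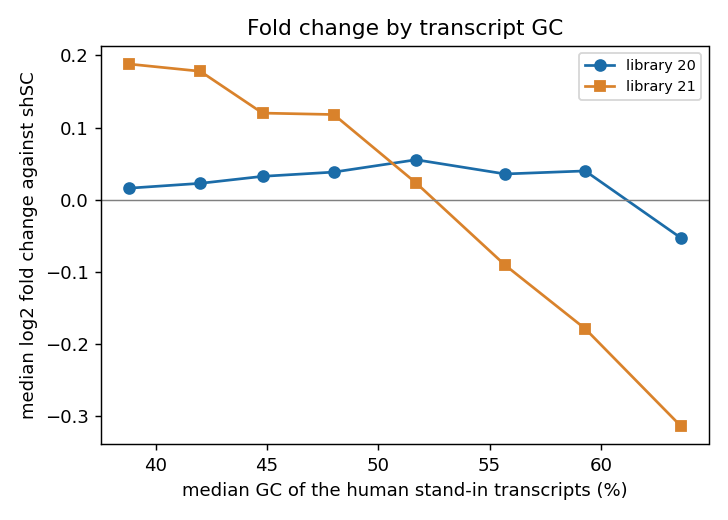
Median log2 fold change against shSC over 8 groups of genes ordered by the GC of human stand-in transcripts; circles are library 20 and squares library 21. Library 21 falls from 0.19 to -0.31 and library 20 lies between -0.05 and 0.06.

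Other lists did not pass camera. Among growth factors and receptor kinases (35 tested, adjusted p = 0.609), Btc and Areg (-1.64) fell, 2 also adjusted over the list alone, and Ereg had -0.68. Of 11 Notch pathway genes Jag1, a Notch ligand gene, fell from 2701 to 998 and 1152 scaled counts (-1.33), 1 also adjusted over the list alone (0.286). Of 25 ferroptosis and iron genes Nox1 fell and 3 were lower adjusted over the list alone (0.453). Over the list alone 1 gene each was higher among 18 TGF-beta targets (Fst, 1.20; 0.574) and lower among 22 glycolysis genes (Eno2, -1.14; 0.574). Fst passed over all genes with DESeq2 (0.0252) and without the filter (0.0055), and Eno2 without the filter (0.0148) and after length and GC correction (0.0311). No member passed either way among 26 Hippo pathway components (0.286; Fat1 0.67), 19 merlin relatives and partners (0.171; Pak1 0.57), 7 epithelial markers (0.794), 10 mesenchymal transition genes (0.453; Fn1 -1.03), 14 integrins (0.654; Itgb3 -1.54), 23 MHC class I genes (0.83), 24 NF-kB targets (0.782; Ptgs2 -0.69), 37 Myc and ribosome biogenesis genes (0.171; Ncl 0.64), 37 ATF4 response genes (0.746), 22 unfolded protein response genes (0.654; Dnajb9 -0.76), 32 NRF2 targets (0.609), 35 lysosome and autophagy genes (0.535; Ctsl -0.73) and 15 Wnt targets (0.721). Of these genes Dnajb9 passed after length and GC correction (adjusted p = 0.0327) and Fn1 without the filter (0.0389). Medians and camera directions differed in sign for glycolysis, ferroptosis and ATF4 genes, whose medians of 0.03, 0.07 and 0.03 stood beside a downward test. For mesenchymal genes the mean difference from other genes was 0.04 with a downward test and a median of -0.11.

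Among 6 mesothelial markers Krt7 rose, and adjusted over the list alone Krt7 was higher and Krt19 (-0.86) lower (adjusted p = 0.782), with Krt19 passing without the filter (0.0321), a median of -0.26, a mean difference from other genes of 0.14 and a downward test. Msln, which encodes mesothelin, had 7397 scaled counts in shSC and a log2 fold change of 0.34. Markers of other cell types were few in the table. Of 20 macrophage markers 5 were tested, 0 passed over all genes tested and Lyz2 (2.19 in library 20 and 0.92 in library 21), which passed without the filter (0.0349), was higher adjusted over the list alone (0.794); the mean difference was 0.03 beside a downward test. Of 20 fibroblast and smooth muscle markers 3 were tested, and Gsn (0.68) was higher over the list alone (0.574). Of the lymphocyte and endothelial markers 2 each were tested, and Ecscr (-1.44) was lower adjusted over the list alone.

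**Figure D3:**
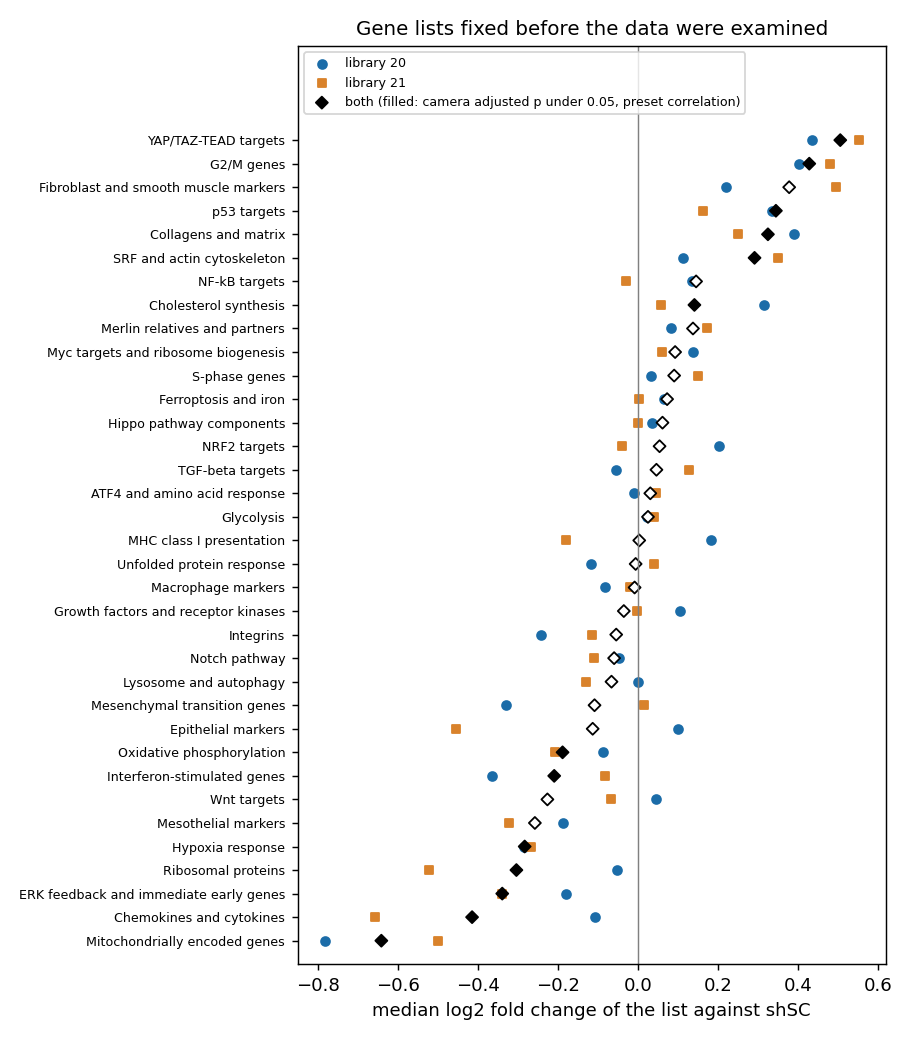
Median log2 fold change of each tested list against shSC; circles are library 20, squares library 21 and diamonds both together, filled where camera's adjusted p was under 0.05 at the preset correlation. YAP/TAZ-TEAD targets have a median of 0.51 and mitochondrially encoded genes -0.64.

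The libraries 20 and 21 moved genes in a correlated way against their shared shSC library. Pearson's r of the log2 fold changes across genes was 0.658, where simulated unchanged libraries sharing 1 control gave a mean of 0.499, and the covariance was 0.189 against a simulated 0.0896, a difference of 0.099. The sign was shared by 71.9% of genes (66.6% simulated). At least 2-fold higher in both were 171 genes, including Cyr61 and Ccl9, and at least 2-fold lower 167, including Nf2 and Nox1; simulations gave means of 66.0 and 35.8 (at most 91 and 50), and independent lists would share 8.37 and 12.3. The shSC library could not be split, so part of the excess may come from it. Part may also come from genes noisier than the simulated dispersion trend, which could make the simulated values too low. Singly, 327 and 328 genes were at least 2-fold higher and 374 and 420 lower in libraries 20 and 21.

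**Figure D4:**
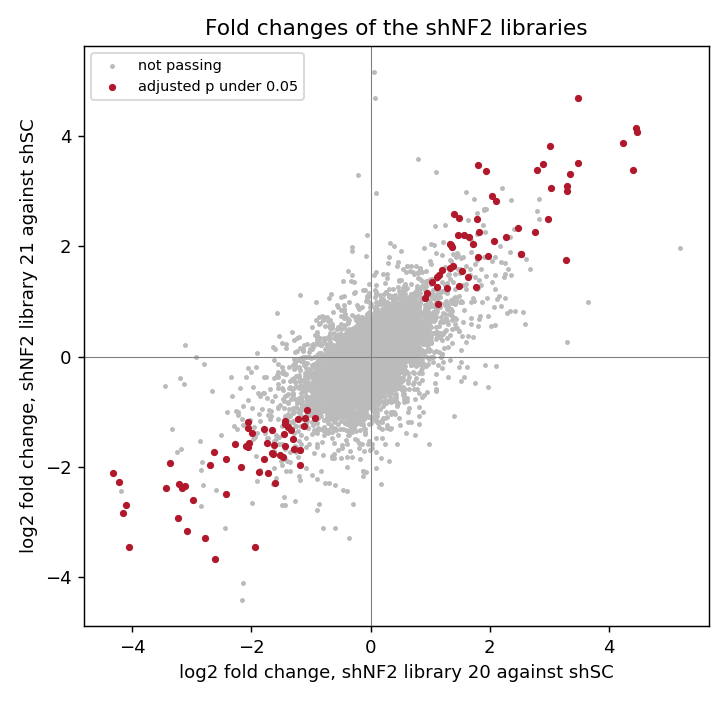
Log2 fold change of library 20 (horizontal) and library 21 (vertical) against shSC for 12813 genes. Red points passed the test, which takes its spread from the difference between these libraries and so largely fixes a shared sign. The 108 red points lie on the same side of 0 in both libraries, and r across genes is 0.658.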

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

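The corrections for length and GC were chosen after the data had been seen, and the other settings were planned. Leaving out the filter raised the prior degrees of freedom from 11.9 to 31, which can lower p-values of genes at any level. Without a filter, limma called 110 genes higher and 122 lower. Under quantile normalization it called 0 and 0 (prior degrees of freedom 3.65 against 11.9; 882 genes at an unadjusted p under 0.05), and without a variance trend 0 and 0 (prior degrees of freedom 4.09; 1036 genes), while edgeR and DESeq2 called 81 and 98. edgeR called 29 higher, so 35.8% of its calls were higher against 49.1% with limma. After length and GC correction 46 were higher and 65 lower, and 82 of the 89 called genes with a stand-in remained; on the same genes uncorrected 50 were higher and 55 lower. With stand-ins by symbol alone, which cover under 80% of genes, 65 were higher and 89 lower, against 35 and 35 uncorrected; why the correction moved the calls differently on the gene sets was not tested. Nf2 kept its size with a lost call under quantile normalization (-1.72) and without a trend (-1.70). Genes at least 2-fold higher in both libraries numbered 98 with pseudocount 10, 75 with a mean of at least 50, 489 at 1.5-fold and 63 at 3-fold, and lower genes 86 with a mean of at least 50, 510 at 1.5-fold and 49 at 3-fold; fewer genes tested or another fold limit shows the cause, except for the pseudocount, where it was not tested. Leaving out an shNF2 library left no residual degrees of freedom and no test; the size rule then gave 327 to 328 higher and 374 to 420 lower genes, because 1 library has to pass. The correlation was 0.633 without a filter, 0.643 under quantile normalization and 0.715 after correction; the cause was not tested. Of the gene lists 13 passed, 0 with an estimated correlation, for which camera has 1 residual degree of freedom (smallest unadjusted p 0.151, where a statistic of 12.7 is needed for 0.05), and 7 under quantile normalization; the cause of the latter was not tested. Camera's direction, which never passed, turned upward for mesothelial markers after correction (mean difference 0.24, already positive before) and, with a mean of at least 50, for macrophage markers (0.26, already positive before) and Wnt targets (0.078, from -0.16). Of 165 other named genes none turned direction under the settings with a test; calls were lost for 37 under quantile normalization, 37 without a trend, 9 with TMM, 8 with robust moderation, 6 with DESeq2, 5 with edgeR, 1 with pseudocount 10 and 1 after correction. Calls were gained for 10 without a filter (Ankrd37, Cnn2, Eno2, Fn1, Fst, Krt19, Lyz2, Oas1a, Sat1, Thbs1), 4 with DESeq2 (Cnn2, Fst, Oas1a, Sat1) and 2 after correction (Dnajb9, Eno2). The genes gained without a filter had all been tested with it, so their gain is no separate support for them. Genes with a mean under 10 scaled counts were not tested, and depth limits the low genes. No paired analysis was possible because the shSC group has 1 library.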

Other observations

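The gene families and the genes that differ between the shNF2 libraries were chosen after their values were seen, as were the test of scaling, the tests on the most abundant transcripts and the other splits of the libraries. The interleukin 36 gene Il1f6 fell from 27573 scaled counts in shSC to 7975 and 7594 (limma adjusted p = 0.00184), Slurp1 from 292 to 87.9 and 67.1, and Sprr2k from 300 to 70.1 and 97.2. All 7 tested small proline-rich protein genes were below shSC in both libraries with a median log2 fold change of -1.14, and 1 of them passed. Of 12 clade B serpins 3 fell (Serpinb2, Serpinb7, Serpinb11), with a family median of 0.05. Of 3 mast cell protease genes Mcpt1 and Mcpt2 fell and Mcpt8 had a log2 fold change of 0.75. Of 4 CCN family genes Cyr61, Ctgf and Wisp1 rose and Nov had -1.15. Tmsb4x, which encodes an actin monomer-binding peptide, fell from 286240 to 68832 and 91901. No family member changed sign under TMM or quantile scaling.

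The shNF2 libraries differed from each other by at least 2-fold in 491 genes. Thbs1 had 99.3 scaled counts in shSC, 173 in library 20 and 1196 in library 21, and Nt5e 360, 227 and 791. Saa3 had 253, 996 and 173, and Plet1 821, 440 and 119. No test of these differences was possible with 1 library each.

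The G2/M list was higher in shNF2 at the preset correlation (adjusted p = 0.852 with an estimated correlation). A trend over transcript length and GC as the whole cause was argued against: after each library's trend was subtracted, the list's mean log2 difference from other genes was 0.32, from 0.39 before over the same genes. Since stand-ins are human, part of a trend could remain. A change in the share of dividing cells at lower Nf2 stays open and was not tested. The S-phase list had a median log2 fold change of 0.09 and did not pass at the preset correlation (camera adjusted p = 0.404).

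The ribosomal protein list was lower in shNF2, mostly in library 21, at the preset correlation (adjusted p = 0.852 with an estimated correlation). Subtracting the length and GC trend left a mean difference of -0.22, from -0.26 over the same genes, so the trend alone is unlikely to be the whole cause. Under quantile normalization the difference was -0.043, which cannot decide on scaling. That method gives the highest ranks the same values in every library, so it may remove a shared fall of abundant genes. Rpl19, Rpl34, Rpl13a and Rps27a had means of 28867 to 85291 scaled counts. With TMM the list's call was kept. A difference between libraries that depends on level stays open, and so does a property of library 21, as the median without it was -0.05. The YAP/TAZ-TEAD target list kept a mean difference of 0.49 after the same correction (adjusted p = 0.852 with an estimated correlation, uncorrected).

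The mitochondrially encoded list was lower in shNF2 at the preset correlation (adjusted p = 0.852 with an estimated correlation). Nuclear genes within the range of the list's levels had a median log2 fold change of 0.00724, but they are 37.6% of tested genes, so scaling holds that median near 0 and it decides nothing. The 164 nuclear genes from the list's lower quartile to its highest level had -0.22 (95% bootstrap interval -0.28 to -0.15) against -0.64 for the list. These genes thus fell less than the list in these libraries. The interval resamples genes as if independent and holds no spread between libraries, so it cannot decide on a loss of abundant transcripts as the whole cause. Such a loss stays open, most of all for the highest levels, where 27 nuclear genes above the upper quartile had -0.38 (-0.49 to -0.18). Under quantile normalization the list's mean difference from other genes was -0.25, from -0.49 as deposited. A factor per library moves the list and the other genes nearly alike, so it can hardly make this difference. The calls of all 35 tested lists were the same with TMM. Quantile normalization changes values by rank, so a difference between libraries that depends on level stays open. A biological change that lowers mitochondrial transcripts also stays open and was not tested.

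With 3 libraries there are 3 ways to set 1 against 2, too few for a share under 0.05. A way that groups shSC with an shNF2 library counts their difference as spread. This lowers its calls whatever made shSC differ, so the counts below do not bear on the cause. The real one gave 108 genes and was the only 1 of the 3 to give as many. The highest of the others gave 0 (limma, with 234 and 775 genes at an unadjusted p under 0.05).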
